A study of Mus musculus with 4 samples.

How the data were processed

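Total RNA was extracted from the tumours with Trizol and cleaned on spin columns, and biotin-labelled cRNA was hybridised to the arrays, per the labels. The deposited values are 1 linear intensity for each of 45101 probe sets on each of 4 arrays, and how the authors summarised probes, corrected the background and scaled the arrays is not given in the sources used here. The values run from 0 to about 10806, are not whole numbers, and 79 to 134 values on an array are exactly 0; array medians of 35.6 to 40.8 show that the arrays were not set to a common median. No detection call or depth was used, and the number of arrays limits the precision. Nothing in the labels beyond a tumour number says that the tumours of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. No batch or date was given.

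Probe sets were named through the platform annotation table: of 45037 probe sets other than the 64 controls, 34945 had 1 gene symbol, 932 several and 9160 none. Symbols were looked up by Entrez ID in a RefSeq table of assembly GRCm38.p6, used for names only, which held 34754 of the 34958 probe sets with a single symbol in the annotation table and changed 0 symbols. No coordinates are given. Of 429 distinct symbols on the gene lists, 31 were not analysed here because no probe set was named with them.

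The log2 of the intensity plus 16 was used, so that fold changes of dim genes are understated. Control probe sets and the dimmest 40% of probe sets by their mean over the 4 arrays were left out, which kept 27022, of which 22555 had 1 symbol. For each gene the probe set with the highest mean over the 4 arrays was tested, which gave 13331 genes. Of the 74 genes past the threshold, 37 had more than 1 probe set kept and 6 had one with a difference of the opposite sign (Cxcl12, Cxcl9, Lbh, Myo1d, Pcgf6 and Rint1). The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), without a term for the tumour number. Tumour numbers 1 and 2 occur in both groups, and nothing in the labels ties equal numbers together. Plots were drawn with matplotlib.

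The lists of pathway genes and cell type markers were written before the data were examined, 29 in all. The 27 with at least 5 members left after the filter on dim probe sets were tested. Limma's camera (preset inter-gene correlation 0.01) compared each with all other genes, adjusted over the 27 lists. Camera with an estimated correlation and fry were run beside it. For each list, members past the threshold were counted over all genes and with p-values adjusted over the list alone. Some measured genes stand on more than 1 list (Tgfb1, Ccn2, Fosl1 and Vegfa).

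Named genes followed a rule fixed before the data were examined: all probe sets of Jun, Etv6 and Ntrk3; the 10 largest rises and 10 largest falls among genes past the threshold with groups that do not overlap and a higher group mean above the median of all probe sets; from each list up to 4 members past the threshold or, where none passed, the 2 with the largest difference; and every AP-1 subunit. Genes named outside the rule, as members of lists or as counts, were chosen after their values were seen.

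The fit was tested on simulated data for the same 13331 genes and 4 arrays. It called 83% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, and called 11 unchanged genes. The changed genes were drawn from bright genes only. Values were drawn with the variances that the same fit had estimated, so the simulation cannot test that variance model. With no change put in, 0 genes and 0 lists were called, and 1 list shifted on purpose was called. Genes were simulated independently of each other, so the list results do not cover lists whose members move together. Alternatives fixed in advance were no filter on dim probe sets or 60% left out, quantile normalization, median centring, pseudocounts of 1 and 64, the mean of a gene's probe sets, every probe set separately, no intensity trend, a robust variance, the replicate block, each array left out in turn, adjusted p thresholds of 0.10 and 0.01, and the other list tests. With an array left out, the lone tumour of its group was assumed to vary like the other group.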

Results

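Gene expression was measured in 4 mouse mammary tumours on Affymetrix mouse genome arrays, with 1 array for each tumour. The tumours grew in nude mice that had been transplanted with Eph4 cells, an established mouse mammary epithelial cell line. In 2 tumours, called EN here, the cells carried ETV6-NTRK3, a fusion oncogene that joins the transcription factor gene ETV6 to the kinase domain of the neurotrophin receptor gene NTRK3. In the other 2 tumours, called EN-TAM67, the same cells also expressed TAM67, a dominant negative form of c-Jun, the AP-1 transcription factor subunit. The comparison addressed how far mammary tumour formation by the fusion works through AP-1. The median intensity of an array was 35.6 and 35.9 in the EN tumours and 38.1 and 40.8 in the EN-TAM67 tumours. Across genes, the arrays of a pair from the same group correlated at 0.952 for EN and 0.952 for EN-TAM67, and pairs from different groups at 0.932 to 0.946 (genes are not independent replicates). All differences below are EN-TAM67 minus EN on the scale log2(intensity + 16), with n = 2 tumours in each group, and adjusted p-values for genes are from limma.

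Car3 and Cd36 rose and Eln fell in EN-TAM67 tumours. Of the gene lists, adipocyte genes had a median difference of 1.55 and interferon response genes of -0.75. Both passed limma's camera with a preset correlation, and both had adjusted p = 0.505 with an estimated correlation. The largest rise was in Car3, a carbonic anhydrase abundant in fat and muscle, at 1292 ± 992 (SD) against 95.9 ± 45.0 intensity units, a log2 difference of 3.36 ± 0.39 (SE, adjusted p = 4.7e-04). The Car3 difference was 2.50 without EN-TAM67 tumour 2 and 4.23 without EN-TAM67 tumour 1. Its call was lost with a robust variance and without the intensity trend. Cd36, a fatty acid transporter, rose from 17.9 ± 1.68 to 225 ± 74.3 units (2.80 ± 0.24, adjusted p = 1.6e-05), a size that rests on the pseudocount because the EN level lies below the array medians (1.80 with a pseudocount of 64). The largest fall was in Eln, which encodes elastin, from 1173 ± 469 to 102 ± 3.09 units (-3.28 ± 0.25, adjusted p = 4.9e-06).

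Of 13331 genes tested, 18 were higher and 56 lower in EN-TAM67 tumours at an adjusted p under 0.05, and 65 of these 74 changed at least 2-fold (16 higher and 49 lower). With each array centred on its median, 7 genes were higher and 48 lower. All 74 genes had groups that did not overlap, whereas over all genes tested the groups did not overlap in 40.2%, where chance gives 33.3%. The counts moved with single arrays: 71 genes were higher and 80 lower without EN tumour 1, 39 and 85 without EN tumour 2, 17 and 26 without EN-TAM67 tumour 1, and 11 and 11 without EN-TAM67 tumour 2. Without the intensity trend in the variance model 5 genes passed (Cd36, Cxcl14, Eln, Gzmd and Gzme).

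Signs of RNA quality differed between the groups. The ratio of 3' to 5' signal was 0.938 and 1.04 for Gapdh in the EN tumours against 1.17 and 1.11 in the EN-TAM67 tumours, and 1.11 and 1.19 against 1.31 and 1.34 for beta-actin. The control probe sets for 18S ribosomal RNA averaged 5.43 and 6.40 on the log2 scale in EN and 6.76 and 7.43 in EN-TAM67 tumours. Each of these measures was higher in both EN-TAM67 tumours than in either EN tumour, beside every gene group described below.

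Beside Car3 and Cd36, the 10 largest rises included 3 genes that stand, like Car3 but unlike Cd36, on the adipocyte list. Fabp4, the fatty acid binding protein of adipocytes, rose by 2.47 ± 0.45 (SE, adjusted p = 0.0217), Adipoq, which encodes the hormone adiponectin, by 2.33 ± 0.51 (adjusted p = 0.0485), and Retn, which encodes resistin, by 1.59 ± 0.34 (adjusted p = 0.0481). Foxp2, a forkhead transcription factor, rose from 268 ± 60.3 to 1219 ± 439 units (2.09 ± 0.25, adjusted p = 4.7e-04). The others were 5930403N24Rik (1.86 ± 0.32), Flrt3, a leucine-rich repeat membrane protein (1.66 ± 0.28), Insl6, a member of the insulin-like family (1.58 ± 0.27), and Xist, the RNA that coats the inactive X chromosome (1.52 ± 0.29). With a pseudocount of 64, 5930403N24Rik was at 1.08, Flrt3 at 0.94 and Insl6 at 0.97. Without EN-TAM67 tumour 1 the calls of 5930403N24Rik (1.34), Flrt3 (1.48) and Xist (1.06) were lost, and without EN-TAM67 tumour 2 those of Flrt3 (1.85) and Insl6 (1.35). Xist measured 644 ± 265 units in EN and 1899 ± 838 in EN-TAM67 tumours.

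After Eln, the 10 largest falls included Cyp11a1, which catalyses the first step of steroid hormone synthesis (-2.67 ± 0.32, adjusted p = 4.7e-04), and Gzme (-2.66 ± 0.36, adjusted p = 0.0016) and Gzmd (-2.05 ± 0.31, adjusted p = 0.0052), proteases of cytotoxic granules. Gzme read 0.854 and 7.41 units in the EN-TAM67 tumours, below the array medians, so the size of its difference rests on the pseudocount; with a pseudocount of 64 it was -1.35, and Gzmd was at -1.10 and Slit3 at -0.93. Cd200, a surface protein that restrains myeloid cells, fell by 1.96 ± 0.23, and the chemokine Cxcl14 fell from 407 ± 11.1 to 94.8 ± 20.6 units (-1.94 ± 0.22, adjusted p = 4.7e-04). The guidance ligand Slit3 fell by 1.91 ± 0.40, and the interferon-inducible GTPases Iigp1 and Irgm2 each fell by 1.83 (SE 0.32 and 0.24). Without EN-TAM67 tumour 2 the calls of Iigp1 (-1.24) and Slit3 (-1.77) were lost, and without EN tumour 2 that of Gzmd (-1.95). The chemokine Cxcl9 averaged -2.47 ± 0.46 (adjusted p = 0.0236), with 221 ± 220 units in EN tumours. Without EN tumour 1 the same probe set differed by -1.34, and another probe set of the gene, then the brighter one, by 0.41.

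**Figure D1:**
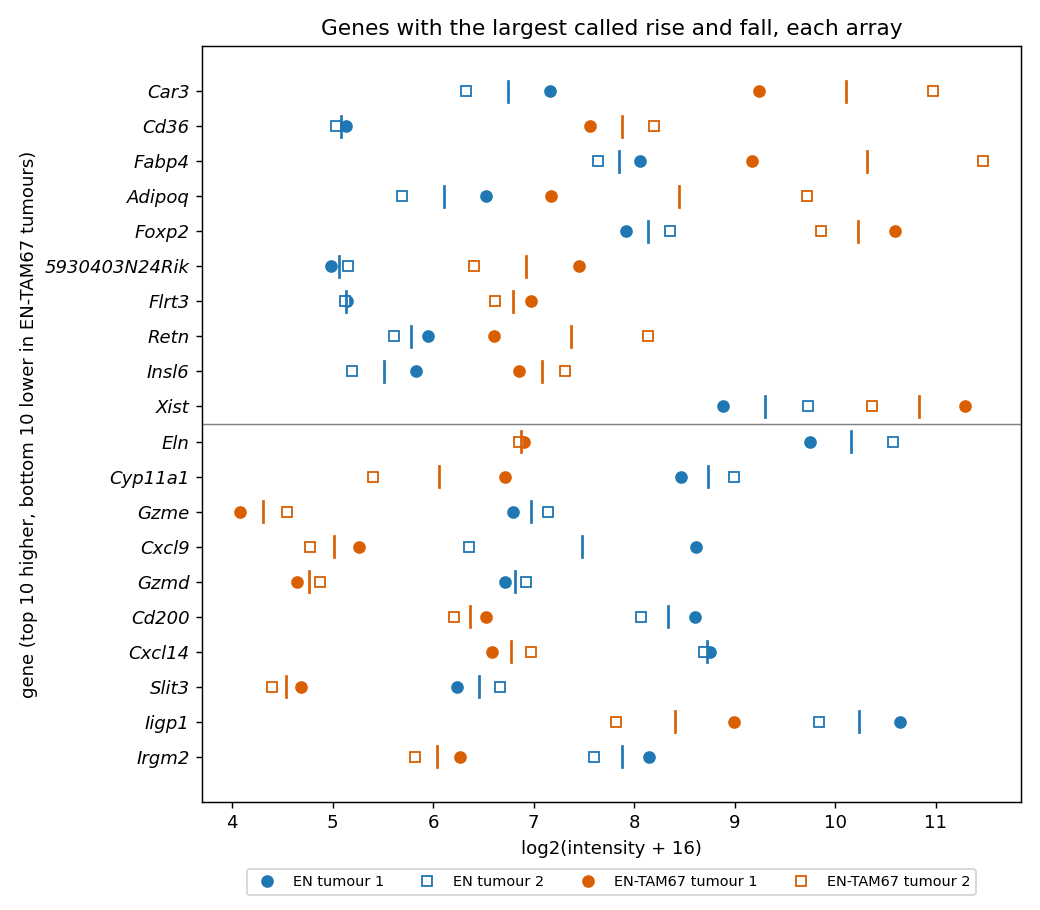
Each point is 1 array, at log2(intensity + 16) on the x axis, for the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold. Blue is EN and orange EN-TAM67, short bars are group means of 2 arrays; Eln lies at 102 ± 3.09 units (SD) in EN-TAM67 against 1173 ± 469 in EN tumours, while the EN tumours lie far apart for Cxcl9.

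No probe set of the genes behind the constructs passed the threshold. The brighter of 2 Jun probe sets read 130.4 ± 2.89 units in EN and 132 ± 31.1 in EN-TAM67 tumours, and the other differed by -0.35. The 2 Etv6 probe sets differed by -0.13 and -0.030, and the Ntrk3 probe sets by -0.50 to 0.16. The groups did not overlap in the dimmer Jun probe set or in the Ntrk3 probe set at -0.50, which read 31.2 ± 1.84 units in EN and 17.3 ± 0.727 in EN-TAM67 tumours, nor in an Ntrk3 probe set at 0.13, which read 15.6 ± 0.914 and 18.6 ± 0.999. Whether these probes read the human or truncated transcripts of the constructs is not given in the sources used here, so they check nothing about the labels.

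No AP-1 subunit and no gene of the AP-1 target list passed the test over all genes. Of 12 AP-1 subunits, 0 passed over all genes and 0 when adjusted over the list alone. Jund, at 2054 ± 204 units in EN and 1361 ± 144 in EN-TAM67 tumours, differed by -0.59 ± 0.19 (SE, adjusted p = 0.265), or by -0.044 with its probe sets averaged, Fosb by -0.66, Junb by -0.43 and Fos by -0.33. Fosl1 was at 0.45, Atf2 at 0.29, Atf3 at 0.22, Batf at 0.21, Fosl2 at 0.12, Jdp2 at -0.027 and Batf3 at -0.15. Junb was at -0.16 without EN-TAM67 tumour 1 and -0.70 without EN-TAM67 tumour 2, and Fosl1 at 0.22 without EN tumour 1 and 0.69 without EN tumour 2. As a list the subunits did not pass limma's camera (median -0.014, adjusted p = 0.603), and the median was -0.10 without EN-TAM67 tumour 1, -0.088 without EN-TAM67 tumour 2, -0.023 without EN tumour 1 and -0.0069 without EN tumour 2, -0.11 with median centring and 0.060 with the dimmest 60% of probe sets left out. Of 20 AP-1 target genes, 0 passed over all genes and 0 adjusted over the list alone, and 15 were negative. The median was -0.19 and the list passed camera with a preset correlation (adjusted p = 0.0399). It had adjusted p = 0.505 with an estimated correlation. It missed the threshold without EN tumour 2 (median -0.11) or without EN-TAM67 tumour 1 (-0.26) or 2 (-0.19), with quantile normalization (-0.21), and with the dimmest 60% of probe sets left out (-0.16), and its median was -0.29 with median centring. In the same tumours the fibroblast list stood at a median of -0.51 and the adipocyte list at 1.55. The AP-1 target genes with the largest values were Mmp3, a matrix metalloproteinase, at -1.03 ± 0.32 and Tgfb1 at -0.73 ± 0.21.

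The adipocyte list had the median farthest from 0 among the 27 lists tested, in the tumours whose Gapdh 3' to 5' ratios were the higher ones (1.17 and 1.11). Of 12 list members named on the array, 9 were left after the filter on dim probe sets. These 9 all had positive differences, with a median of 1.55. Of these, 4 rose over all genes (Car3, Fabp4, Adipoq and Retn) and 6 when adjusted over the list alone (camera adjusted p = 9.6e-11). The list had adjusted p = 0.505 with an estimated correlation. The median stood at 0.74 in EN-TAM67 tumour 1 and 2.36 in EN-TAM67 tumour 2, both relative to the EN mean. Without EN-TAM67 tumour 2 the list median was 0.83, and Fabp4 (1.32), Adipoq (1.06) and Retn (0.83) no longer passed, while without EN-TAM67 tumour 1 the list median was 2.36 and Adipoq was at 3.60. With no filter on dim probe sets the list median was 0.89. Of 7 skeletal muscle genes, 1 rose, over all genes and adjusted over the list alone: Myh1, a fast myosin heavy chain, by 1.39 ± 0.23 (adjusted p = 0.0092). This call was lost in 3 of 14 other fits, without EN-TAM67 tumour 2 (1.30), with its probe sets averaged (1.22) and without the intensity trend, and the difference was 0.94 with a pseudocount of 64. The muscle list had a median of 0.26 (camera adjusted p = 0.0165). It had adjusted p = 0.505 with an estimated correlation, and it missed the threshold without EN tumour 2 (0.32), without EN-TAM67 tumour 2 (0.27) and with no filter on dim probe sets (0.19), with a median of 0.16 after median centring.

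Lists of stromal and vascular cell markers were lower in EN-TAM67 tumours, where the Gapdh 3' to 5' ratios were 1.17 and 1.11 against 0.938 and 1.04. For fibroblast genes the median of 16 members was -0.51, with 14 negative, 0 that fell over all genes and 11 that fell when adjusted over the list alone (camera adjusted p = 3.6e-09). This list had adjusted p = 0.505 with an estimated correlation. Its largest members were Lum, which encodes the matrix proteoglycan lumican (-1.07 ± 0.26), and Thy1 (-0.96 ± 0.32). All 10 endothelial genes tested were negative, with a median of -0.39, 0 that fell over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0012). The endothelial list had adjusted p = 0.598 with an estimated correlation, and values were -0.74 for Cdh5, VE-cadherin, and -0.70 for Eng, endoglin. Without EN tumour 2 the fibroblast median was -0.30 and the endothelial median -0.22, and the endothelial list no longer passed; without EN tumour 1 the endothelial median was -0.66. Of 15 TGF-beta response genes 13 were negative, with a median of -0.32, 0 that fell over all genes and 1 adjusted over the list alone (camera adjusted p = 2.8e-04). They had adjusted p = 0.505 with an estimated correlation; Tgfb1 was at -0.73 and Id3 at -0.65. Among 11 genes of the epithelial-mesenchymal transition, 0 fell over all genes and 2 fell adjusted over the list alone, with Sparc at -0.84 (adjusted p = 0.0527) and the repressor Snai1 at -0.81. Their median of -0.088 passed camera (adjusted p = 0.0406), with adjusted p = 0.734 with an estimated correlation. That median was 0.048 without EN tumour 2 and 0.017 with every probe set tested separately, -0.31 without EN tumour 1, -0.30 without EN-TAM67 tumour 1 and -0.19 with median centring. The call also ended without EN-TAM67 tumour 2 (-0.025), with quantile normalization (-0.088), with no filter on dim probe sets (-0.088) and with a gene's probe sets averaged (-0.033). Smooth muscle and pericyte genes did not pass (7 tested, median -0.20, camera adjusted p = 0.328, 0 past the threshold over all genes and 0 adjusted over the list alone), with Pdgfrb at -0.45 and Des at 0.44. Their median was -0.079 without EN tumour 2 and -0.33 without EN tumour 1.

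Interferon response and macrophage genes were also lower in EN-TAM67 tumours, beside the lower fibroblast list (-0.51) and the higher 18S signal (6.76 and 7.43 against 5.43 and 6.40). The interferon list had a median of -0.75 over 13 members, 12 of them negative. Irf7, a transcription factor of the interferon response, fell by 1.16 ± 0.25 (adjusted p = 0.0449) and Oasl2 by 1.04 ± 0.22 (adjusted p = 0.0449), which made 2 that fell over all genes and 8 adjusted over the list alone. Each of these 2 calls was lost in 9 of 14 other fits, among them those without EN tumour 1 (-0.83 and -0.85), without EN-TAM67 tumour 1 (-0.96 and -0.92) and without EN-TAM67 tumour 2 (-1.35 and -1.15). The list passed camera (adjusted p = 2.0e-08) and had adjusted p = 0.505 with an estimated correlation. Its median was -0.35 without EN tumour 1 and -1.15 without EN tumour 2. Of 16 macrophage genes 14 were negative, with a median of -0.41, 0 that fell over all genes and 5 adjusted over the list alone (camera adjusted p = 1.8e-07). The macrophage list had adjusted p = 0.520 with an estimated correlation, and its median was -0.21 without EN-TAM67 tumour 2 and -0.69 without EN-TAM67 tumour 1. Lyz2, lysozyme, was at -0.88 ± 0.20 (adjusted p = 0.064) and the complement gene C1qb at -0.82 ± 0.20. Neutrophil genes (6 tested, median -0.14, camera adjusted p = 0.603) and lymphocyte genes (9 tested, median 0.0093, mean -0.12, camera adjusted p = 0.475) did not pass, with 0 members past the threshold over all genes and 0 adjusted over the list alone. The direction of both medians rested on single arrays: that of neutrophil genes was 0.27 without EN-TAM67 tumour 2, 0.071 without EN tumour 1 and -0.37 without EN-TAM67 tumour 1, and that of lymphocyte genes -0.20 without EN tumour 2, -0.14 without EN-TAM67 tumour 2, 0.14 without EN tumour 1 and 0.14 without EN-TAM67 tumour 1. Values were -0.23 for S100a9, -0.21 for Csf3r, -0.80 for Prf1 (perforin) and -0.45 for Cd4. Nerve and Schwann cell genes (6 tested) had a median of -0.34 (camera adjusted p = 0.175), with 0 that fell over all genes and 1 adjusted over the list alone, Ncam1 at -0.79 and S100b at -0.64.

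**Figure D2:**
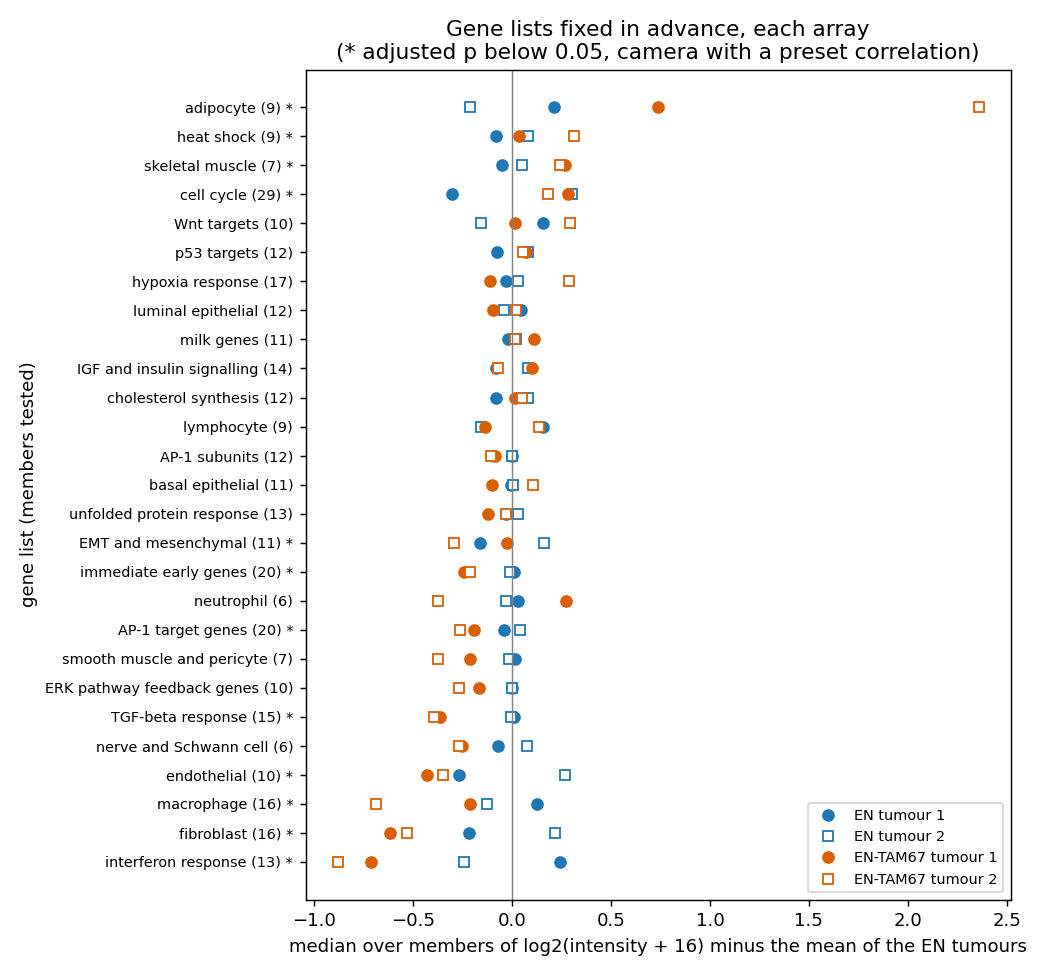
Each point is 1 array: the median, over the tested members of a list, of log2(intensity + 16) minus the mean of the EN tumours, with the number of members tested in brackets and an asterisk where camera with a preset correlation passed. The adipocyte list lies at 0.74 and 2.36 in the EN-TAM67 tumours and the interferon list at -0.72 and -0.88, while the points of the 2 EN tumours lie on both sides of 0 by construction.

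Spry1, a feedback inhibitor of receptor tyrosine kinase signalling, fell by 1.05 ± 0.22 (adjusted p = 0.0402). This made 1 of 10 ERK feedback genes that fell, over all genes and adjusted over the list alone (median -0.22, camera adjusted p = 0.0512). The ERK feedback list had adjusted p = 0.505 with an estimated correlation. The list passed in 5 other fits: without EN tumour 2 (-0.21), without EN-TAM67 tumour 1 (-0.27), with a pseudocount of 1 (-0.25), with a gene's probe sets averaged (-0.25) and with every probe set tested separately (-0.21); it stood at -0.14 without EN-TAM67 tumour 2. The call of Spry1 was lost in 5 of 14 other fits, those without EN-TAM67 tumour 1 (-0.88) or 2 (-1.21) among them. Of 20 immediate early genes 18 were negative, with a median of -0.14, 0 that fell over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0014). They had adjusted p = 0.505 with an estimated correlation, and the median was -0.27 without EN tumour 2, -0.21 without EN tumour 1, -0.21 without EN-TAM67 tumour 1 and -0.25 without EN-TAM67 tumour 2, -0.22 with quantile normalization and -0.24 with median centring. Ccn1, a matricellular protein, was at -0.88 ± 0.22 and Ier2 at -0.71 ± 0.22. The IGF binding protein genes Igfbp3 (-1.33 ± 0.22, adjusted p = 0.0092) and Igfbp7 (-0.88 ± 0.18, adjusted p = 0.0354) fell, which made 2 of 14 IGF and insulin signalling genes over all genes and 2 adjusted over the list alone. The call of Igfbp7 was lost in 7 of 14 other fits, among them those without EN tumour 1 (-0.78) and without EN-TAM67 tumour 1 (-0.73) or 2 (-1.02), and its difference was -0.44 with its probe sets averaged; that of Igfbp3 was lost in 3, without EN-TAM67 tumour 1 (-1.42) or 2 (-1.23) and without the intensity trend. That list had a median of 0.044, a mean of -0.14 and camera direction down (adjusted p = 0.169). The median was -0.18 without EN tumour 1, -0.19 without EN tumour 2, -0.069 without EN-TAM67 tumour 1 and 0.10 without EN-TAM67 tumour 2. Wnt targets (10 tested) had a median of 0.16 (camera adjusted p = 0.402), with 0 that rose over all genes and 1 adjusted over the list alone; Wnt10a was at 0.69 and Nkd2 at -0.28. The Wnt median was -0.021 without EN tumour 2, -0.0029 without EN-TAM67 tumour 2, 0.24 without EN tumour 1 and 0.29 without EN-TAM67 tumour 1.

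The cell cycle list had a median of 0.20 over 29 genes, 23 of them positive, with 0 that rose over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0052). It had adjusted p = 0.734 with an estimated correlation. Its median was -0.12 without EN tumour 1 and 0.45 without EN tumour 2, and it also missed the threshold without EN-TAM67 tumour 1 (0.18). With median centring it was 0.099. Kif11, a mitotic kinesin, was at 0.75 ± 0.25 and Cenpf at 0.65 ± 0.26. The heat shock list passed camera (9 tested, median 0.26, adjusted p = 0.0425) with 0 members past the threshold over all genes and 0 adjusted over the list alone. It had adjusted p = 0.520 with an estimated correlation. It missed the threshold without EN tumour 1 (0.11), without EN-TAM67 tumour 2 (0.033), with median centring (0.17), with no filter on dim probe sets (0.26) and with a gene's probe sets averaged (0.18), and its median was 0.41 without EN tumour 2. Hsph1 was at 0.56 and Hsp90aa1 at 0.43.

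Markers of the epithelial cells themselves did not shift as lists. Luminal epithelial genes (12 tested) had a median of 0.077 with camera direction down (adjusted p = 0.883), basal epithelial genes (11 tested) a median of -0.016 with direction up and a mean of 0.053 (adjusted p = 0.879), and milk genes (11 tested) a median of 0.064 with direction down and a mean of -0.026 (adjusted p = 0.973). Leaving out single arrays turned each of these medians: the luminal one was -0.022 without EN tumour 2 and -0.097 without EN-TAM67 tumour 2, the basal one 0.021 without EN tumour 1 and 0.12 without EN-TAM67 tumour 1, and the milk one -0.12 without EN tumour 2 and -0.047 without EN-TAM67 tumour 1. Values were 0.56 for Pgr, the progesterone receptor, -0.47 for Cldn7, 0.67 for Krt14, -0.63 for Krt5, -1.14 for the casein gene Csn1s2a and 0.60 for the lipid droplet gene Plin2. Nor did p53 targets (12 tested, median 0.13, adjusted p = 0.883), hypoxia genes (17 tested, 0.085, adjusted p = 0.328), the unfolded protein response (13 tested, -0.047, adjusted p = 0.395) or cholesterol synthesis (12 tested, median 0.023 with direction down, mean -0.0015, adjusted p = 0.973) pass camera. The hypoxia list passed camera with a preset correlation without EN-TAM67 tumour 1 (median 0.29). With all 4 arrays it had adjusted p = 0.898 with an estimated correlation. Its median was -0.11 without EN-TAM67 tumour 2 and -0.014 with median centring, and the cholesterol median was -0.11 without EN tumour 1 and 0.16 without EN tumour 2. The p53 median was between 0.025 (without EN tumour 1) and 0.072 (without EN-TAM67 tumour 2) with any 1 array left out, and the unfolded protein median was -0.12 without EN-TAM67 tumour 2. In these lists Gadd45a was at -0.47, Phlda3 at -0.38, the hexokinase gene Hk2 at 0.57, Adm at 0.46, Herpud1 at -0.51, Sdf2l1 at -0.44, Lss at 0.57 and Dhcr7 at -0.38. Each of the lists in this paragraph had 0 members past the threshold over all genes and 0 adjusted over the list alone. Keratinocyte (4 genes left after the filter on dim probe sets, median 0.34, Sbsn 0.72, Krt10 -0.37) and red blood cell genes (2 left, median -0.24, Hba-a1 -0.32, Hbb-b2 -0.17) were too few for the list test. They had 0 members past the threshold over all genes or adjusted over the list alone. Probe sets with several gene names entered neither list, and of 10 red blood cell symbols 5 were named on the array. In all, 12 of 27 lists passed camera with a preset correlation (4 higher and 8 lower), 0 with an estimated correlation (1 list at an unadjusted p under 0.05, smallest adjusted p = 0.505) and 0 with limma's fry (3 lists at an unadjusted p under 0.05, smallest adjusted p = 0.164). Correlation among members was not the only reason. For TGF-beta response genes it was estimated at -0.069, yet the unadjusted camera p was 5.1e-05 with the preset and 0.0495 with the estimate.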

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

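The measurements below lie outside the gene-level comparison and were singled out after the data were seen. When every probe set was tested separately, 11 probe sets that carry no gene name or several names in the annotation used here passed the threshold (limma); they enter no count of genes. The control probe sets for 18S ribosomal RNA differed by 1.18 on the log2 scale between the groups, higher in EN-TAM67 tumours.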

How the results depend on the processing

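All alternatives but 1 were planned before the data were examined, and the cause of a change was not tested unless stated. The compared values are 18 genes higher, 56 lower, 65 changed at least 2-fold and 12 lists shifted. Over single genes and alternatives, 321 results stayed on their side of the threshold, 117 lost the call and 1 called result reversed. For list medians these numbers were 375, 19 and 3, and 6 gained a call (5 for ERK feedback genes and 1 for hypoxia genes). A turn of direction was counted only for results called in the main fit, so uncalled results that changed sign are among those that stayed. Of the other genes named with a call, Adipoq and Retn each lost it in 11 of 14 fits besides the replicate block, Cxcl9 in 8, Fabp4 in 7, Xist in 6, Slit3 in 5 of 10, Iigp1 and Myh1 in 3, Flrt3 in 3 of 13, Car3, Cyp11a1 and Insl6 in 2, 5930403N24Rik in 2 of 13, Foxp2, Cd200 and Irgm2 in 1 and Gzmd in 1 of 13; Gzme kept it in all 10 fits that tested it. Cd36, Cxcl14 and Eln, 3 genes, passed in all 15 other fits, and 7 genes did when the fit without the intensity trend was set aside (Cd200, Foxp2, Gbp6 and Irgm2 in addition). Quantile normalization gave 9 higher, 29 lower and 37 changed 2-fold; median centring gave 7 higher; averaging a gene's probe sets gave 7 higher, 28 lower and 34 changed 2-fold; no intensity trend gave 1 higher, 4 lower and 5 changed 2-fold. A pseudocount of 64, which shrinks folds of dim genes by construction, gave 34 changed 2-fold. At a threshold of 0.10, 29 genes were higher, and at 0.01, 4 were higher and 13 lower. The labels tie equally numbered tumours by the number alone, and their deviations correlated at -0.065 across genes. The BioB control probe sets averaged 8.60 (EN) and 8.65 (EN-TAM67) on the log2 scale in tumours 1, against 9.16 and 9.11 in tumours 2. Processing shared by number is therefore not excluded. With the replicate block, which leaves fewer degrees of freedom, 3 genes were higher, 8 lower and 11 changed 2-fold. Lists shifted were 0 with an estimated correlation and 0 with fry. With each array left out in turn, higher genes ranged from 11 to 71, lower genes from 11 to 85, 2-fold changes from 22 to 141 and lists from 8 to 12. Cxcl9 ranged from -3.60 to 0.41 and reversed without EN tumour 1, where another probe set became the brightest (the first one stood at -1.34, a value added after seeing the data); the cell cycle median ranged from -0.12 (without EN tumour 1) to 0.45. The median for the epithelial-mesenchymal transition ranged from -0.31 to 0.048 (without EN tumour 2) and was 0.017 with every probe set tested separately. Intensities near the array medians, 35.6 to 40.8 units, lie close to the dimmest values kept, so differences of such genes are the least certain in size.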

Other observations

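Beyond the lists fixed in advance, 5 gene families were put together after the genes past the threshold had been seen, so their tests are no independent evidence of direction. Gbp2, Gzma, Gzmb, Ltbp2 and Mfap5 also stand on the lists fixed in advance. Antigen presentation genes had a median difference of -0.96 over 16 members, 15 of them negative; the invariant chain gene Cd74 (-1.48 ± 0.22, SE, adjusted p = 0.0047 from limma), H2-K1 (-1.18 ± 0.22, adjusted p = 0.0224) and H2-Ab1 (-1.26 ± 0.25, adjusted p = 0.0284) fell, and the 13 others had a median of -0.81. The median of all 16 was -0.50 without EN tumour 1 and -1.25 without EN tumour 2. All 12 interferon-inducible GTPases were negative (median -1.22), 6 fell (among them Gbp6, -1.66, Igtp, -1.48, and Gm4951, -1.43), and the other 6 had a median of -0.88. Granzymes had a median of -0.89 over 8 members; Gzmc (-1.73), Gzmd and Gzme fell, while Gzmb was at 0.27 and Gzmm at 0.31, and the 5 others had a median of -0.37, with 3 negative. Among 12 elastic fibre genes with a median of -0.42 only Eln fell (the 11 others had a median of -0.34), and the cross-linking enzyme gene Loxl1 was at -1.05 (adjusted p = 0.0653). Genes of fat uptake and storage had a median of 0.19 over 15 members, and were at -0.12 without EN-TAM67 tumour 2, 0.52 without EN-TAM67 tumour 1 and 0.32 without EN tumour 2. Among them Cd36 and Fabp5 (1.16 ± 0.23, adjusted p = 0.0308) rose and the lipase gene Lpl was at 1.71 (adjusted p = 0.0754). The 3 negative members were Thrsp (-0.87), Elovl6 (-0.47) and Cebpa (-0.20). With an estimated correlation the adjusted p of these 5 lists lay between 0.148 and 0.325.

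Further genes that fell, picked after their values were seen, were the proteoglycan gene Bgn (-1.05 ± 0.20, SE, limma adjusted p = 0.0280), the protease inhibitor Timp3 (-1.17 ± 0.24, adjusted p = 0.0354), the Wnt modulator Sfrp2 (-1.54 ± 0.32, adjusted p = 0.0411), the chemokine Cxcl12 (-1.42 ± 0.22, adjusted p = 0.0052, with another probe set of opposite sign) and Apoe (-0.98 ± 0.19, adjusted p = 0.0243). The cell cycle inhibitor Cdkn1b fell by 1.03 ± 0.21 (adjusted p = 0.0402). Of 3 genes on the Y chromosome, looked up because Xist rose, Uty differed by 0.0071, Eif2s3y by 0.034 and Kdm5d by -0.16, all at intensities of 11.9 to 74.0 units, near the dim end of the arrays.

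The tests of adipose tissue, macrophages, a single EN tumour and a shared host share below were chosen after the results were seen; the tests of array scaling were written down before their results. The rise of adipocyte genes was not removed by quantile normalization (median 1.56 against 1.55). The log2 medians of the arrays lay between 5.69 and 5.83, so rescaling could hardly have moved the list. A common difference in scale of that size is too small to account for the rise. The normalization adds no further evidence. Whether adipose tissue of one composition mixed into both EN-TAM67 samples accounts for it cannot be decided here. The log2 ratio of the rise in tumour 2 to that in tumour 1 ranged over 2.46 among the 6 members that rose adjusted over the list alone. Log2 ratios from 1.48 to 3.26 lay within the wide 95% ranges of all of them. Those ranges were simulated from the residual spread of the fit, which holds the distance between the 2 EN-TAM67 tumours. That distance widens the ranges, so their overlap is no support. For Cd36 the log2 ratio was 0.75 (simulated 95% range -0.020 to 1.52), a range that only just reaches the ratios of the list. Its share from adipose tissue therefore cannot be told apart from a rise of its own. An effect of TAM67 on the tumour cells stays open and untested.

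The fall of interferon response genes was -0.78 after quantile normalization against -0.75. Here too the close array medians left little room for another outcome. Those medians were higher in EN-TAM67 tumours, opposite to the fall, which argues against a common difference in scale. A single EN tumour with a high interferon signal may account for part of the size, since the median without EN tumour 1 was -0.35, although the list still passed camera there. Fewer macrophages and a weaker interferon response cannot be told apart here. The interferon median lay lower than the macrophage median by a difference of -0.34, with a permutation p of 0.105 (100000 permutations of genes between the lists, two-sided). That p treats genes as independent, although members moved together within both lists (estimated correlation 0.46 for interferon and 0.51 for macrophage genes). It does not measure the spread between tumours, so it decides nothing. An effect of TAM67 is open and untested.

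The lower medians of the fibroblast, endothelial and macrophage lists were kept after quantile normalization, where the highest of the 3 was -0.40. With such close array medians this outcome was nearly fixed. The array medians were higher in EN-TAM67 tumours, opposite to the lower lists, which argues against a common difference in scale. Camera with an estimated correlation gave these lists adjusted p = 0.505, 0.598 and 0.520, and 0 of their members fell over all genes. One smaller share of all host cells would lower the markers of every host cell type, and 2 host lists, adipocyte and skeletal muscle, passed camera with a preset correlation in the opposite direction, but neither with an estimated correlation (adjusted p = 0.505 for both) nor with fry (0.379 and 0.308). The argument against that share rests on the adipocyte members themselves: 9 of 9 left after the filter on dim probe sets were positive and 6 rose when adjusted over the list alone. Their median lay between 0.83 and 2.36 with each array left out in turn, and the list median was 0.89 with no such filter. The members moved together (estimated correlation 0.78), so they are not separate pieces of evidence. The muscle call was lost in 3 other fits, so muscle decides nothing here. Fat or muscle next to the tumour, taken along with it, could still go with a smaller share of the other host cells. A lower share of tumour stroma therefore remains open. An indirect effect of TAM67 on gene activity within these host cells is also open and untested. TAM67 itself was expressed in the transplanted cells.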
